A study of Arabidopsis thaliana with 42 samples.

How the data were processed

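The series holds 42 samples, of which the 12 RNA-seq libraries were used and the other 30, from bisulfite sequencing, chromatin immunoprecipitation and genome resequencing, are not analysed here. Per the labels, polyA RNA was taken from 2-week-old seedlings that had been kept cold for 7 days as seed, and each library carries a genotype and a replicate number from 1 to 3. The labels spell the second double mutant ddm1npre1, the deposited columns spell it ddm1nrpe1, and the replicate number with the rest of the genotype ties each column to 1 sample. The authors deposited a table with raw read counts per locus, whole numbers with a different total in each library, and beside them CPM values. The deposited CPM columns, checked against the counts, are the counts over their column sum on a scale with the same total in every library, so they carry no scaling between libraries and were not used for tests. Trimmomatic, TopHat, HTSeq, edgeR, Bowtie2, BSMAP, Picard, SAMtools and deepTools are named in the submitters' processing notes, with the genome build TAIR10 and without roles or versions. Whether replicates are separate cultures, the strand setting, the treatment of reads that match several loci and the annotation behind the counts are not given in the sources used here, and they bear most on transposons and paralogs. Wild-type RNA libraries and the single mutants of the other genes were not analysed here, so every change stands against ddm1.

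The table holds 25069 loci, of which 2 have no count in any library. Names and gene classes come from a RefSeq gene table of assembly TAIR10.1, which lists 22869 of the 22968 loci with a gene identifier, while 2200 loci of all kinds are absent from it. The counts rest on TAIR10, so no coordinates from that table are printed. TE loci are the 1936 with a transposon identifier and 16 others named as transposons, and their families and positions were not used here. Pseudogene, protein-coding, plastid and mitochondrial loci follow the class in that table or the organelle identifier.

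Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci passed filterByExpr on the 4 groups (24839 loci, among them 20210 protein-coding, 1919 TE, 1909 pseudogene, 110 plastid and 46 mitochondrial), and libraries were scaled by TMM. A single model of group means over the 12 libraries (8 residual degrees of freedom) was fitted with robust quasi-likelihood dispersions, and each pair of groups was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over all tested loci, at an adjusted p under 0.05. The standard error of a log2 fold change is approximated as its size over the square root of F. Total counts of 7.84 to 24.8 M per library set the precision. A fold against a group with 0 counts was computed against a floor of 3 counts over its 3 libraries and given as a lower bound, and with 1 to 3 counts the ratio was given with an exact binomial counting interval. Shares of counts were compared with two-sided exact permutation tests, and the share of TE loci called with two-sided Fisher's exact tests.

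Before the data were examined, 21 gene lists were fixed: methyltransferases of DNA and H3K9 (with DDM1, VIM1 and IBM1), DNA demethylation, RdDM machinery, post-transcriptional silencing, genes silenced by DNA methylation, ONSEN copies, DNA damage, immune, wound and jasmonate, heat shock, cold, drought and ABA, clock, flavonoid, aliphatic glucosinolate, flowering, cell division, leaf photosynthesis, root, seed, pollen and senescence. ONSEN, seed and pollen had fewer than 3 tested members and got no list test. The others and the TE loci were tested with camera (preset correlation 0.01), and the pseudogene loci were added as a list after the data had been seen, which made 60 tests over 3 comparisons adjusted together. Camera with an estimated correlation and fry were run beside it. Named genes were set by a rule written at the same time: the mutated genes, then per comparison against ddm1 the 6 TE loci highest and the 4 lowest by log2 fold change and the 6 highest and 6 lowest other loci, among those called, with mean CPM of at least 1 in the higher group and no overlap between libraries, then 2 to 4 members per list by smallest adjusted p, and 3 loci each way between double mutants. Loci named by the rule whose call or value rested on 1 library were left out of the text unless given with that value. Overlaps of calls were set beside independent lists and beside 20 simulations of unchanged groups against the same ddm1 libraries.

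The alternatives were RLE, upper-quartile and TE-free TMM factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of CPM 1 in 3 libraries, the 6 libraries of a comparison alone, the replicate number as a block, a change of at least 2-fold, each library left out in turn and, chosen after seeing the data, the fit without organelle loci. The steps were tested on simulated data for ddm1nrpd1 against ddm1 (24770 loci): 32.8% of loci changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold were called, and 12 of 152 calls (7.89%) were false. The 200 changed loci were drawn from those above a minimum expected count in the smallest library, so recovery at low-count loci was not measured. In the data 11081 of 24839 loci were called in this comparison, and the adjusted p depends on how many loci change. The simulated rates therefore do not give the sensitivity or the false share of the real comparison.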

Results

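RNA was sequenced from 2-week-old Arabidopsis thaliana seedlings grown on plates of nutrient medium under 16 h of light and 8 h of dark at 22 °C. The 12 libraries fall into 4 groups of 3: the single mutant ddm1 and the double mutants ddm1nrpd1, ddm1nrpe1 (spelled npre1 in the labels) and ddm1cmt2. DDM1 is a chromatin remodeller that DNA methylation of transposons in heterochromatin depends on. NRPD1 and NRPE1 are the largest subunits of RNA polymerases IV and V, the polymerases of RNA-directed DNA methylation (RdDM), and CMT2 is a chromomethylase that methylates cytosines outside CG sites. The comparisons ask what loss of either non-CG methylation route adds to ddm1, and whether these routes differ. Total counts ran from 7.84 to 24.8 M per library. Group means were 8.92 ± 1.17 M in ddm1, 18.7 ± 5.35 in ddm1nrpd1, 17.8 ± 1.26 in ddm1nrpe1 and 13.5 ± 3.99 in ddm1cmt2 (SD, n = 3). Replicates of one group correlated at r = 0.974 to 0.993 across genes on the log2 scale, and every pair differed by more than counting noise (chi-square per degree of freedom 3.90 to 24.5). The labels do not say whether the 3 samples of a group came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical.

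In what follows, levels are TMM-normalised CPM (read counts scaled to a common library size) as mean ± SD of 3 libraries, and log2 fold changes are given ± their standard error. A gene is said to rise or fall only where the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was under 0.05. Counting intervals and floors cover counting error only. Fisher's exact tests treat loci as independent, which loci measured in the same libraries are not, so their p-values overstate the evidence. Strand is not stated for the counting, so antisense and overlapping genes cannot be separated, and transposon copies and close paralogs (CAB2 and CAB3, KIN1 and KIN2, the histone H3 genes, the cluster of SNC1 and RPP4) may share reads.

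Loci of transposable elements (TEs) took 6.06% ± 0.472 of counts in ddm1, 5.65% ± 0.466 in ddm1nrpd1, 6.72% ± 0.133 in ddm1nrpe1 and 5.01% ± 0.346 in ddm1cmt2 (SD, n = 3). A two-sided exact permutation test against ddm1 gave p = 0.40, 0.10 and 0.10 for the 3 double mutants in that order, where 0.1 is the smallest p that 3 against 3 libraries allow. Pseudogene loci took 6.08% ± 0.470, 5.98% ± 0.60, 7.25% ± 0.133 and 4.86% ± 0.353 (exact permutation p = 0.80, 0.10 and 0.10). Plastid genes took 1.75% ± 0.201 of counts in ddm1, 0.223% ± 0.0520 in ddm1nrpd1, 0.232% ± 0.0960 in ddm1nrpe1 and 0.870% ± 0.0787 in ddm1cmt2 (exact permutation p = 0.10 for each against ddm1 and 0.90 between ddm1nrpd1 and ddm1nrpe1). Mitochondrial genes took 0.0550% ± 0.00426, 0.0181% ± 0.00204, 0.0213% ± 0.00580 and 0.0424% ± 0.00491 in the same order. The first principal component of log2 CPM held 52.3% of the variance and parted the 6 ddm1nrpd1 and ddm1nrpe1 libraries (54.7 to 83.7) from the 6 ddm1 and ddm1cmt2 libraries (-75.7 to -55.9), as the plastid share did.

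**Figure D1:**
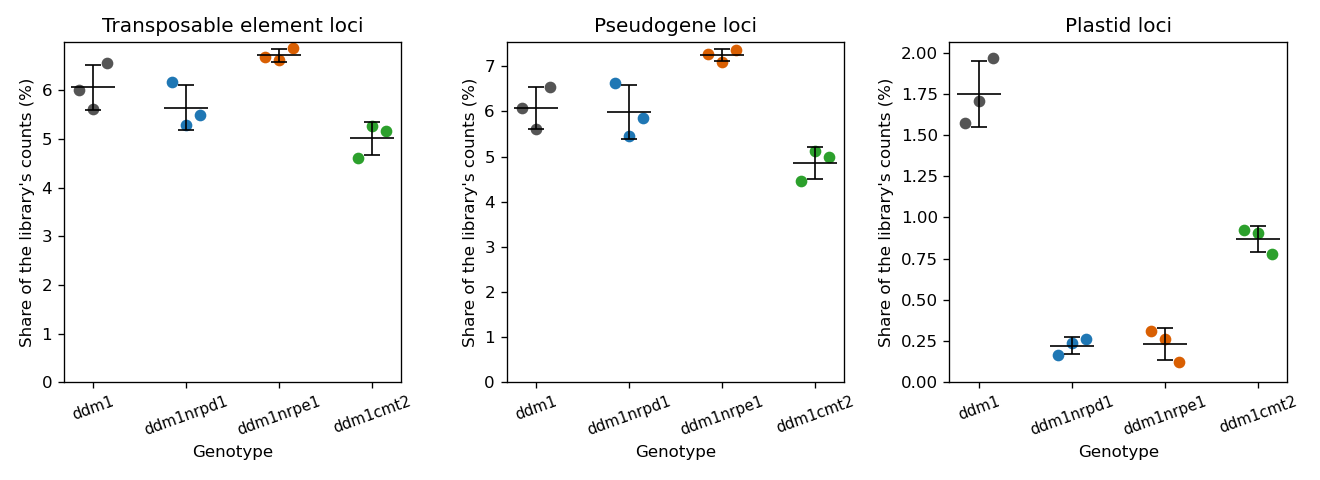
Share of counts (percent) at TE, pseudogene and plastid loci in each library, by group, with points for libraries and bars for mean ± SD (n = 3). Plastid shares lie at 1.75% on average in ddm1 and at 0.223% and 0.232% in ddm1nrpd1 and ddm1nrpe1.

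The mutated genes were read first. NRPD1 (AT1G63020) stood at 5.74 ± 1.27 CPM in ddm1 and rose to 14.1 ± 0.725 in ddm1nrpd1, a log2 fold change of 1.30 ± 0.19 (adjusted p = 7.0e-05), and did not pass the test in ddm1nrpe1 (-0.36 ± 0.21) or ddm1cmt2 (-0.28 ± 0.22). NRPE1 (AT2G40030) rose from 13.1 ± 1.08 to 58.7 ± 5.65 CPM in ddm1nrpe1 (2.16 ± 0.15, adjusted p = 2.2e-08), fell in ddm1nrpd1 (-0.72 ± 0.16) and did not pass in ddm1cmt2 (-0.14 ± 0.16). CMT2 (AT4G19020) was at 31.8 ± 2.99 CPM in ddm1 and 26.8 ± 1.08 in ddm1cmt2 (-0.24 ± 0.11, adjusted p = 0.105, or -0.30 and 0.0458 with upper-quartile factors), and fell in ddm1nrpd1 (-0.63 ± 0.11) and ddm1nrpe1 (-0.90 ± 0.11). DDM1 (AT5G66750) did not pass the test in ddm1nrpd1 (0.12 ± 0.16), ddm1nrpe1 (-0.30 ± 0.16) or ddm1cmt2 (-0.06 ± 0.16), though without ddm1 replicate 1 the ddm1nrpe1 value was -0.44 (adjusted p = 0.0440). Where each lesion lies in its gene is not given in the sources used here, so a transcript's level cannot check a label.

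Against ddm1, the ddm1nrpd1 libraries held more transcript of SDC and less of ROS1 and of most plastid genes, while TE loci moved both ways. SDC (AT2G17690), an F-box gene silenced through methylated repeats at its promoter, rose from 24.5 ± 1.35 to 502 ± 83.7 CPM (4.35 ± 0.21, adjusted p = 1.2e-09). ROS1 (AT2G36490), a DNA glycosylase that removes methylated cytosine, fell from 42.1 ± 3.91 to 2.64 ± 0.672 CPM (-4.01 ± 0.22, adjusted p = 5.0e-09). Across the genome 5693 of 24839 tested loci rose and 5388 fell, of which 2190 and 1565 changed at least 2-fold.

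Among TE loci, 620 of 1919 rose and 477 fell (651 and 503 adjusted over the list alone). The median was 0.11, also with the members at 0 counts at their bound (camera adjusted p = 0.0864). Without ddm1 replicate 3, ddm1nrpd1 replicate 2 or ddm1nrpd1 replicate 3 that camera adjusted p was 0.0365, 0.0211 and 0.0464. At least 2-fold changes numbered 448 upward and 205 downward. Fisher's exact test of TE against other tested loci gave an odds ratio of 1.68 for a rise (p = 1.1e-22) and 1.21 for a fall (p = 5.4e-04). AT4TE21910, AT5TE41245 and AT4TE16540, at 0 counts in all 3 ddm1 libraries, were at least 22.0-fold, at least 21-fold and at least 13-fold higher in ddm1nrpd1, and AT1TE43225 rose from 0.261 ± 0.0959 to 25.9 ± 7.62 CPM (6.63 ± 0.55). In the other direction, AT5TE71590 and AT5TE71595 had 0 counts in ddm1nrpd1 and were at least 123-fold and at least 23.4-fold lower, and AT1TE43430 fell (-4.67 ± 0.65). AT5TE71590 ran parallel to the cell wall gene EXT11, which also had 0 counts in ddm1nrpd1. In replicate 2 it stood at 7.53 against 26.8 CPM in ddm1 and 1.93 against 6.78 in ddm1nrpe1. Whether reads from that gene's transcription make up these TE counts was not tested. Of the pseudogene loci, 565 of 1909 rose and 536 fell (580 and 556 adjusted over the list alone). The median was -0.02, also with the members at 0 counts at their bound, where the mean was 0.21 and the test pointed up (camera adjusted p = 0.330). Both directions were commoner than among protein-coding loci (Fisher's exact test against protein-coding loci, odds ratio 1.51 for a rise, p = 2.3e-14, and 1.53 for a fall, p = 1.4e-14). By count profile, 418 of 1936 TE loci (21.6%) matched a pseudogene locus of their chromosome within 0.2 log2 units, against 105 (5.42%) for random protein-coding loci. The random loci were matched for number per chromosome and not for count level, so level may make up part of this gap. TE and pseudogene loci may still share reads, so like changes in both are not separate evidence. Pseudogene loci are also among the other loci that TE loci were tested against.

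Of the listed genes silenced by DNA methylation, 5 of 10 rose and 2 fell (5 and 2 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.424). While SDC rose, CACTA1 (AT2G12210, -2.99 ± 0.19), a CACTA element, fell. ROS1 belongs to the DNA demethylation list, of which 1 of 9 rose and 3 fell (1 and 3 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.0864). Beside it IDM1 (AT3G14980), a histone acetyltransferase that active demethylation needs, fell (-1.08 ± 0.14) and DML3 (AT4G34060), a glycosylase of the ROS1 family, rose (0.99 ± 0.22). In the list of methyltransferases of DNA and of H3K9, which also holds DDM1, VIM1 (AT1G57820) and IBM1, 2 of 12 rose and 2 fell (2 and 1 adjusted over the list alone). The median was 0.12 (camera adjusted p = 0.996). The number risen was 1 without ddm1 replicate 3 or ddm1nrpd1 replicate 2 and 4 without ddm1nrpd1 replicate 1, and the number fallen was 1 without ddm1 replicate 2 or ddm1nrpd1 replicate 1, 2 or 3. Of these IBM1 (AT3G07610), an H3K9 demethylase, rose (0.65 ± 0.11). For the RdDM machinery 1 of 19 rose and 8 fell (1 and 8 adjusted over the list alone). The median was -0.29 (camera adjusted p = 0.329). Risen members numbered 2 without ddm1nrpd1 replicate 3. With all libraries, the 1 that rose was NRPD1 itself. Of the post-transcriptional silencing genes 2 of 9 rose and 0 fell (1 and 0 adjusted over the list alone). The median was -0.14, where the mean was 0.05 and the test pointed up (camera adjusted p = 0.996). Calls upward came to 1 without ddm1 replicate 1 or 2 or ddm1nrpd1 replicate 2 or 3. Of these AGO2 (AT1G31280), an Argonaute, rose (1.00 ± 0.14). DNA damage response genes held 6 of 18 that rose and 1 that fell (4 and 1 adjusted over the list alone). The median was 0.14 (camera adjusted p = 0.484). The risen count was 2 without ddm1 replicate 1 and 3 without ddm1 replicate 3. Risen ones included GMI1 (AT5G24280, 1.75 ± 0.23), induced by gamma irradiation, and the checkpoint gene RAD17 (AT5G66130, 1.22 ± 0.18).

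In the immune list, 12 of 18 rose and 0 fell (13 and 0 adjusted over the list alone). The median was 2.34, or 2.20 with the members at 0 counts at their bound (camera adjusted p = 9.1e-05 and adjusted p = 0.582 with an estimated correlation). PR1 (AT2G14610) and PR5 (AT1G75040), defence-induced secreted proteins, rose by 7.03 ± 0.75 and 2.71 ± 0.41, the former 7.82 without ddm1 replicate 1 and 6.41 without ddm1 replicate 3. RPP4 (AT4G16860), a resistance gene of the TIR class, rose by 1.62 ± 0.10, and SAG101 (AT5G14930), a partner of EDS1 in immune signalling, by 1.20 ± 0.19. Wound and jasmonate genes divided, in that 5 of 12 rose and 2 fell (5 and 2 adjusted over the list alone). The median was 0.87 (camera adjusted p = 0.104). Falls numbered 1 without ddm1 replicate 1 or ddm1nrpd1 replicate 1 or 3. Without ddm1 replicate 2 that camera adjusted p was 0.0380. Risen members included AOS (AT5G42650, 1.34 ± 0.12) and LOX3 (AT1G17420, 1.64 ± 0.21), enzymes of jasmonate synthesis. Heat shock genes rose in part: 5 of 7 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 1.28 (camera adjusted p = 0.00374 and adjusted p = 0.552 with an estimated correlation). HSFA2 (AT2G26150), a heat stress transcription factor, went from 0.256 ± 0.0690 to 8.20 ± 3.18 CPM (4.97 ± 0.47), and MBF1C (AT3G24500, 1.74 ± 0.27) and HSP70 (AT3G12580, 1.28 ± 0.14) rose too. Of the senescence genes 5 of 7 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 0.97 (camera adjusted p = 0.0124 and adjusted p = 0.552 with an estimated correlation). They included the sugar transporter gene SAG29 (AT5G13170, 3.63 ± 0.31) and the NAC factor gene NAP (AT1G69490, 2.24 ± 0.39). Plastid share fell beside these groups from 1.75% to 0.223%.

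In the same libraries, with their lower plastid share, the aliphatic glucosinolate and flavonoid lists were read next. Of the former 9 of 9 rose and 0 fell (9 and 0 adjusted over the list alone). The median was 0.99 (camera adjusted p = 0.00133 and adjusted p = 0.552 with an estimated correlation). Enzymes of its core and chain-elongation steps, CYP83A1 (AT4G13770, 1.15 ± 0.15) and BCAT4 (AT3G19710, 1.31 ± 0.17), were among them. In the flavonoid list 5 of 11 rose and 0 fell (6 and 0 adjusted over the list alone). The median was 0.92 (camera adjusted p = 6.7e-08 and adjusted p = 0.448 with an estimated correlation). The number risen was 8 without ddm1nrpd1 replicate 1. The biosynthetic enzymes F3H (AT3G51240, 2.89 ± 0.13), CHI (AT3G55120, 2.54 ± 0.13) and FLS1 (AT5G08640, 2.30 ± 0.14) rose. Cold, drought and ABA genes went both ways, in that 3 of 11 rose and 3 fell (3 and 3 adjusted over the list alone). The median was 0.03, where the mean was -0.22 and the test pointed up (camera adjusted p = 0.996). The dehydrin ERD10 (AT1G20450, 0.93 ± 0.13) rose and the cold-induced regulator CBF2 (AT4G25470, -3.08 ± 0.40) fell. So did the clock list, of which 3 of 11 rose and 5 fell (3 and 6 adjusted over the list alone). The median was -0.38, where the mean was 0.57 and the test pointed up (camera adjusted p = 0.329). GI (AT1G22770), an evening-phased clock gene, rose from 1.14 ± 0.241 to 68.9 ± 12.2 CPM (5.93 ± 0.21), PRR7 (AT5G02810, 2.37 ± 0.11) rose and ELF3 (AT2G25930, -1.23 ± 0.12) fell. For flowering time and floral identity 4 of 6 rose and 1 fell (4 and 1 adjusted over the list alone). The median was 1.02 (camera adjusted p = 0.329). The florigen gene FT (AT1G65480, 2.69 ± 0.44) rose and its activator CO (AT5G15840, -1.53 ± 0.27) fell. Few cell division genes passed the test, since 2 of 14 rose and 0 fell (2 and 0 adjusted over the list alone). The median was 0.03 (camera adjusted p = 0.804). One that rose was the replication helicase gene MCM2 (AT1G44900, 0.75 ± 0.15).

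Root transcripts fell unevenly. Of the root markers 1 of 13 rose and 6 fell (3 and 8 adjusted over the list alone). The median was -0.58 (camera adjusted p = 0.00374 and adjusted p = 0.238 with an estimated correlation). Risen members numbered 2 without ddm1 replicate 3. Camera gave adjusted p = 0.0704 and 0.0729 with DESeq2 and limma-voom. The hair gene COBL9 (AT5G49270) fell from 9.16 ± 1.21 to 0.0687 ± 0.0652 CPM (-6.90 ± 0.37), and EXPA7 (AT1G12560), an expansin of root hairs, had a ratio of 287 (counting interval 78.6 to 2381) between ddm1 and ddm1nrpd1. EXT11 (AT5G49080), PRP1 (AT1G54970), XTH12 (AT5G57530) and RHS12 (AT3G10710), cell wall genes, had 0 counts in ddm1nrpd1 and were at least 457-fold, at least 386-fold, at least 198-fold and at least 179-fold lower. Casparian strip genes ESB1 (AT2G28670, -1.23 ± 0.16) and CASP1 (AT2G36100, -1.11 ± 0.16) fell less. Few leaf photosynthesis markers passed the test, where 1 of 14 rose and 1 fell (0 and 1 adjusted over the list alone). The median was 0.03, where the mean was 0.01 and the test pointed down (camera adjusted p = 0.996). Calls upward came to 0 without ddm1 replicate 1 or 3 or ddm1nrpd1 replicate 1 or 3 and 2 without ddm1nrpd1 replicate 2. The 1 that fell was LHCB5 (AT4G10340), a light-harvesting protein of photosystem II (-0.51 ± 0.15). Plastid-encoded genes fell in 102 of 110 cases with a median of -3.84, ATCG01130 among them (-10.01 ± 0.33). Outside these groups, the 6 loci ranked highest by fitted log2 fold change included AGL34 (AT5G26580), a MADS-box gene, and AT4G17820, RSU1 (AT3G48130), AT2G03080 and AT3G15536. These had 0 counts in ddm1 and were at least 20.4-fold, 30.3-fold, 25.3-fold, 19.6-fold and 16.2-fold higher. Lower bounds do not rank loci, so others may have risen further. Seed markers could not be read, because 1 of 12 was in the table and 0 passed the filter. The only measured pollen marker was GEX2 (AT5G49150), uncalled at -0.18 ± 0.24. Of the 5 ONSEN copies among the counted loci, the 1 that passed the filter, AT1G21945, had -3.37 ± 0.35 (adjusted p = 1.8e-06).

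**Figure D2:**
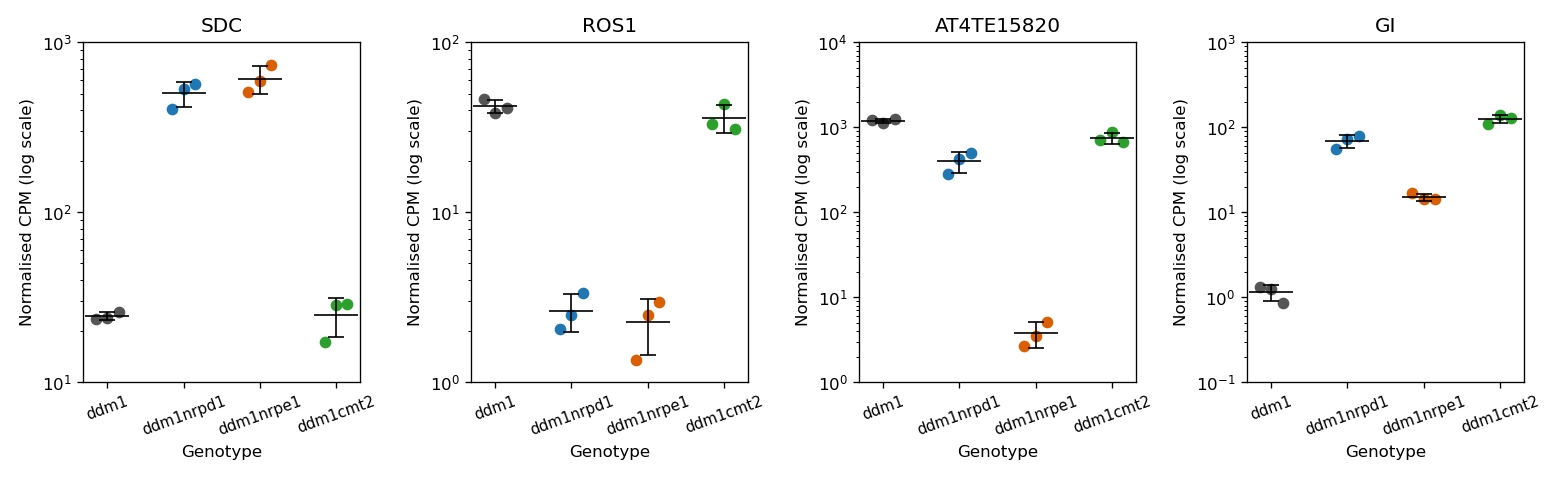
Normalised CPM (log axis) of SDC, ROS1, AT4TE15820 and GI in each library, with points for libraries by group. SDC lies at 24.5 CPM on average in ddm1 and at 502 in ddm1nrpd1, and AT4TE15820 falls to 3.79 in ddm1nrpe1.

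SDC and ROS1 changed in ddm1nrpe1 as they did in ddm1nrpd1, and the abundant TE locus AT4TE15820 fell. SDC rose to 613 ± 114 CPM (4.64 ± 0.21) and ROS1 fell to 2.27 ± 0.823 CPM (-4.20 ± 0.22), while AT4TE15820 fell from 1197 ± 68.8 to 3.79 ± 1.28 CPM (-8.29 ± 0.28, adjusted p = 5.6e-11). It was not lower in ddm1nrpe1 alone, as it stood at 402 ± 109.8 CPM in ddm1nrpd1 and 753 ± 108 in ddm1cmt2, with every library of both below each ddm1 library. PR1 rose by 7.46 ± 0.76, and most plastid genes fell. In all 6582 of 24839 loci rose and 5945 fell, 2661 and 1902 of them at least 2-fold. Without ddm1 replicate 1 the PR1 value was 8.26, and without ddm1 replicate 3 it was 6.82.

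At TE loci 725 of 1919 rose and 424 fell (742 and 442 adjusted over the list alone). The median was 0.17, also with the members at 0 counts at their bound (camera adjusted p = 0.00202 and adjusted p = 0.608 with an estimated correlation). At least 2-fold, 537 went up and 184 down. Fisher's exact test of TE against other tested loci gave an odds ratio of 1.77 for a rise (p = 1.9e-29) and 0.894 for a fall (p = 0.0512). The 4 loci AT4TE18270, AT5TE41430, AT4TE18700 and AT5TE41245 had 0 counts in ddm1 and were at least 46.0-fold, at least 33.0-fold, at least 22.7-fold and at least 17.9-fold higher. AT4TE15825 and AT4TE15835, numbered close to AT4TE15820, fell too (-11.56 ± 0.40 and -6.64 ± 0.38), the first at -12.72 without ddm1nrpe1 replicate 3, and AT3TE47880 was at least 20.1-fold lower. AT4TE15825 stood at 251 ± 7.25 CPM in ddm1, 102 ± 30.4 in ddm1nrpd1 and 171 ± 24.9 in ddm1cmt2. Pseudogene loci rose more often than protein-coding loci did (Fisher's exact test against protein-coding loci, odds ratio 1.65 for a rise, p = 3.4e-22, and 1.05 for a fall, p = 0.431). Of the class 678 of 1909 rose and 467 fell (687 and 491 adjusted over the list alone). The median was 0.09, also with the members at 0 counts at their bound (camera adjusted p = 0.00374 and adjusted p = 0.665 with an estimated correlation). Here limma-voom gave camera adjusted p = 0.101.

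Genes silenced by DNA methylation went down more often than up: 2 of 10 rose and 5 fell (2 and 5 adjusted over the list alone). The median was -0.42, where the mean was 0.20 and the test pointed down (camera adjusted p = 0.854). The transposon genes VANA21 (AT2G23500, -1.74 ± 0.18) and CACTA1 (-1.23 ± 0.18) and the resistance gene SNC1 (AT4G16890, -0.38 ± 0.10) fell beside the rise of SDC. In the RdDM machinery list 2 of 19 rose and 11 fell (2 and 11 adjusted over the list alone). The median was -0.52 (camera adjusted p = 0.104). The risen count was 1 without ddm1 replicate 1 or ddm1nrpe1 replicate 2. With all libraries, NRPE1 itself was 1 of the 2 that rose. With limma-voom the list had camera adjusted p = 0.0371. Those that fell included CLSY1 (AT3G42670), a partner of polymerase IV (-1.81 ± 0.19), DCL3 (AT3G43920), the Dicer of small interfering RNAs (-1.20 ± 0.17), and the ATPase gene MORC6 (AT1G19100, -0.69 ± 0.13). DNA demethylation genes split, in that 2 of 9 rose and 3 fell (2 and 3 adjusted over the list alone). The median was -0.14 (camera adjusted p = 0.216). IDM1 fell (-0.82 ± 0.14) and XRCC1 (AT1G80420), a repair scaffold, rose (0.67 ± 0.10). Of the methyltransferase list 2 of 12 rose and 3 fell (1 and 3 adjusted over the list alone). The median was -0.29 (camera adjusted p = 0.253). Rises numbered 1 without ddm1 replicate 1, 2 or 3 or ddm1nrpe1 replicate 1, 2 or 3, and falls numbered 6 without ddm1nrpe1 replicate 3. CMT2 was among the 3 that fell. Few post-transcriptional silencing genes passed, since 1 of 9 rose and 0 fell (1 and 0 adjusted over the list alone). The median was -0.02, where the mean was 0.16 and the test pointed up (camera adjusted p = 0.804). The number risen was 2 without ddm1 replicate 1. AGO2 was the 1 that rose (1.18 ± 0.14). DNA damage genes went both ways: 3 of 18 rose and 5 fell (3 and 4 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.663). RAD17 rose (1.36 ± 0.18), and the kinase gene ATM (AT3G48190, -0.60 ± 0.12), the cyclin CYCB1;1 (AT4G37490, -0.94 ± 0.21) and the cell cycle inhibitor SMR5 (AT1G07500, -1.55 ± 0.38) fell.

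Of the immune list 16 of 18 rose and 1 fell (17 and 1 adjusted over the list alone). The median was 3.15, or 3.07 with the members at 0 counts at their bound (camera adjusted p = 1.0e-05 and adjusted p = 0.552 with an estimated correlation). RPP4 (1.66 ± 0.10), SAG101 (1.93 ± 0.19) and the salicylic acid receptor gene NPR1 (AT1G64280, 0.79 ± 0.11) rose. Wound and jasmonate genes parted ways, in that 6 of 12 rose and 3 fell (7 and 3 adjusted over the list alone). The median was 0.89 (camera adjusted p = 0.329). AOS rose (1.57 ± 0.12) while VSP2 (AT5G24770), a jasmonate-induced storage protein, and MYC2 (AT1G32640), the main jasmonate transcription factor, fell (-2.10 ± 0.27 and -0.76 ± 0.12). Heat shock genes again rose in part: 5 of 7 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 1.81 (camera adjusted p = 0.0220 and adjusted p = 0.633 with an estimated correlation). HSFA2 rose by 3.66 ± 0.53, MBF1C by 1.97 ± 0.27 and HSP70 by 0.93 ± 0.14. In the senescence list 6 of 7 rose and 0 fell (6 and 0 adjusted over the list alone). The median was 1.43 (camera adjusted p = 0.0354 and adjusted p = 0.552 with an estimated correlation). Without ddm1nrpe1 replicate 3 camera gave adjusted p = 0.0646. SAG29 (3.06 ± 0.32), NAP (1.85 ± 0.39) and the chlorophyll-breakdown gene NYE1 (AT4G22920, 0.77 ± 0.16) were among the risen. Of the flavonoid genes 6 of 11 rose and 2 fell (6 and 2 adjusted over the list alone). The median was 0.70 (camera adjusted p = 0.0752). Fallen members numbered 1 without ddm1 replicate 1 or 2 or ddm1nrpe1 replicate 1 or 3 and 0 without ddm1nrpe1 replicate 2. F3H rose by 1.53 ± 0.13, CHI by 1.42 ± 0.13 and CHS (AT5G13930), the entry enzyme, by 0.87 ± 0.12. Camera's adjusted p for the flavonoid list was 0.0247 without ddm1nrpe1 replicate 2 and 0.0494 with DESeq2. Aliphatic glucosinolate genes differed among themselves, since 3 of 9 rose and 1 fell (3 and 1 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.684). Calls upward came to 5 without ddm1 replicate 2, and calls downward came to 2 without ddm1 replicate 1 or 3 and 3 without ddm1nrpe1 replicate 3. CYP83A1 (0.75 ± 0.15) and BCAT4 (0.84 ± 0.17) rose and their regulator MYB28 (AT5G61420, -0.50 ± 0.11) fell. As in ddm1nrpd1, the plastid share was low beside these groups (0.232%).

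Most clock genes fell: 2 of 11 rose and 8 fell (2 and 8 adjusted over the list alone). The median was -1.33 (camera adjusted p = 0.0144 and adjusted p = 0.518 with an estimated correlation). The morning gene CCA1 (AT2G46830, -2.03 ± 0.12) and ELF3 (-1.67 ± 0.12) fell, and GI (3.74 ± 0.22) and PRR7 (2.98 ± 0.11) were the 2 that rose. More cold genes fell than rose, as 1 of 11 rose and 3 fell (1 and 3 adjusted over the list alone). The median was -0.05 (camera adjusted p = 0.424). The risen count was 2 without ddm1 replicate 2 and 3 without ddm1nrpe1 replicate 1. CBF2 fell (-3.75 ± 0.45), CBF3 (AT4G25480), its neighbour and paralog, had a ratio of 37.9 (counting interval 9.80 to 324) between ddm1 and ddm1nrpe1, and ERD10 rose (0.51 ± 0.13). Flowering genes included CO, which fell (-2.91 ± 0.31), and SEP3 (AT1G24260), a floral MADS-box gene, which rose (2.31 ± 0.52). Of the list 2 of 6 rose and 1 fell (2 and 1 adjusted over the list alone). The median was 0.81, where the mean was 0.33 and the test pointed down (camera adjusted p = 0.996). Rises numbered 1 without ddm1 replicate 3 or ddm1nrpe1 replicate 3, and falls numbered 2 without ddm1nrpe1 replicate 3. Of the cell division genes 0 of 14 rose and 8 fell (0 and 8 adjusted over the list alone). The median was -0.49 (camera adjusted p = 0.0721). The mitotic cyclins CYCB1;3 (AT3G11520) and CYCB1;2 (AT5G06150) and the cytokinesis syntaxin KNOLLE (AT1G08560) fell by 1.08 ± 0.19, 1.00 ± 0.20 and 1.00 ± 0.18. Camera's adjusted p for this list was 0.0392 without ddm1 replicate 1, 0.0251 without ddm1nrpe1 replicate 3, 0.0335 with limma-voom and 0.0498 without organelle loci.

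More root markers fell than rose, as 1 of 13 rose and 9 fell (1 and 9 adjusted over the list alone). The median was -1.08 (camera adjusted p = 0.00374 and adjusted p = 0.201 with an estimated correlation). The number risen was 2 without ddm1 replicate 3. Those that fell included the auxin transporter gene PIN2 (AT5G57090, -1.27 ± 0.12), the radial patterning gene SHR (AT4G37650, -1.08 ± 0.13), ESB1 (-1.56 ± 0.17) and CASP1 (-1.30 ± 0.16). Leaf photosynthesis markers did not move together, as 5 of 14 rose and 4 fell (5 and 4 adjusted over the list alone). The median was -0.05, where the mean was 0.07 and the test pointed up (camera adjusted p = 0.895). The light-harvesting genes CAB2 (AT1G29920, 0.92 ± 0.14), LHCB3 (AT5G54270, 0.78 ± 0.14) and LHCA1 (AT3G54890, 0.84 ± 0.16) rose. Plastid-encoded genes fell in 101 of 110 cases with a median of -3.74, including ATCG01130 (-10.68 ± 0.34), ATCG00220 (-9.50 ± 0.21), ATCG00810 (-9.11 ± 0.25) and ATCG00800 (-8.77 ± 0.26). Other loci at 0 counts in ddm1 were RSU1 (at least 30.7-fold higher), the receptor kinase gene CRK38 (AT4G04510) (at least 24.0-fold), the glutathione transferase gene GSTU12 (AT1G69920) (at least 22.1-fold) and AT4G17820 (at least 16.7-fold). GEX2 fell (-0.89 ± 0.25), and AT1G21945 of the ONSEN list had -3.59 ± 0.37 (adjusted p = 1.4e-06).

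**Figure D3:**
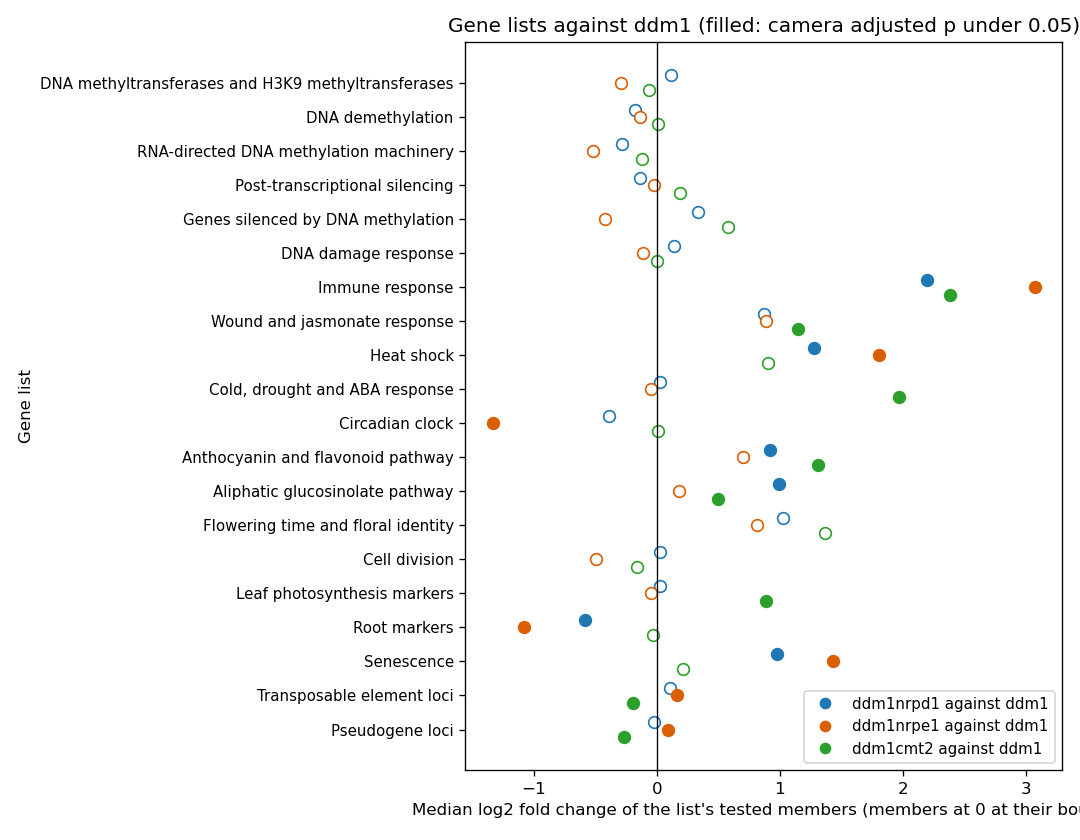
Median log2 fold change of each gene list in the 3 double mutants against ddm1, with members at 0 counts at their bound and filled symbols where the camera adjusted p was under 0.05. The immune list lies at 2.20, 3.07 and 2.39, and the cold, drought and ABA list at 1.97 in ddm1cmt2.

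Against ddm1, the ddm1cmt2 libraries held more transcript of cold and ABA genes and of GI, and less of LHY, while more TE loci fell than rose. COR15A (AT2G42540), a chloroplast protein of cold acclimation, rose from 2.40 ± 0.786 to 45.8 ± 12.7 CPM (4.27 ± 0.29, adjusted p = 1.9e-07), and GI from 1.14 ± 0.241 to 126 ± 14.5 (6.80 ± 0.20, adjusted p = 4.4e-12). LHY (AT1G01060), a morning clock transcription factor, fell from 647 ± 60.7 to 24.7 ± 2.56 CPM (-4.71 ± 0.13, adjusted p = 2.0e-12). In total 4569 of 24839 loci rose and 4402 fell, 1487 and 1163 of them at least 2-fold.

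TE loci fell more often than they rose: 157 of 1919 rose and 433 fell (153 and 420 adjusted over the list alone). The median was -0.19, also with the members at 0 counts at their bound (camera adjusted p = 0.00437 and adjusted p = 0.660 with an estimated correlation). At least 2-fold, 67 went up and 181 down. Fisher's exact test of TE against other tested loci gave an odds ratio of 0.374 for a rise (p = 4.2e-39) and 1.39 for a fall (p = 2.0e-08). AT3TE90545 (2.97 ± 0.50) and AT1TE41580 (2.34 ± 0.52) rose, AT2TE38910 (-3.71 ± 0.41) and AT3TE52420 (-5.13 ± 0.37) fell. Without ddm1cmt2 replicate 2 the value of AT3TE52420 was -5.99. This locus was also low in ddm1nrpe1, at 0.165 to 0.539 CPM against 19.8 to 35.1 in ddm1. The pseudogene class, which may share reads with TE loci, ran the same way (Fisher's exact test against protein-coding loci, odds ratio 0.353 for a rise, p = 1.0e-44, and 2.16 for a fall, p = 5.2e-42). In it 161 of 1909 rose and 548 fell (162 and 551 adjusted over the list alone). The median was -0.27 (camera adjusted p = 7.4e-04 and adjusted p = 0.660 with an estimated correlation). The lean downward was not particular to these 2 classes. Of the 645 nuclear loci outside the TE, pseudogene and protein-coding classes, 70 rose and 159 fell (10.9% and 24.7%). Protein-coding loci, most of those that TE loci were tested against, leaned the other way (20.7% rose, 15.7% fell).

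Genes silenced by DNA methylation rose in more cases than they fell, as 6 of 10 rose and 2 fell (6 and 2 adjusted over the list alone). The median was 0.58 (camera adjusted p = 0.0981). Fallen members numbered 1 without ddm1 replicate 3 or ddm1cmt2 replicate 1, 2 or 3. CACTA1 (1.30 ± 0.18), the transposon gene VANC21 (AT2G23480, 0.95 ± 0.14) and SNC1 (0.73 ± 0.10) rose and QQS (AT3G30720, -0.57 ± 0.13), an orphan gene with a methylation-sensitive promoter, fell. Of the RdDM machinery 0 of 19 rose and 2 fell (0 and 1 adjusted over the list alone). The median was -0.12 (camera adjusted p = 0.621). Calls downward came to 1 without ddm1 replicate 1, 2 or 3 or ddm1cmt2 replicate 1 or 3. RDM1 (AT3G22680), a DNA-binding component, fell (-0.69 ± 0.18). Of the methyltransferase list 3 of 12 rose and 2 fell (3 and 2 adjusted over the list alone). The median was -0.06 (camera adjusted p = 0.997). The risen count was 1 without ddm1 replicate 3 or ddm1cmt2 replicate 2, and the fallen count was 0 without ddm1 replicate 1 or ddm1cmt2 replicate 1 and 1 without ddm1 replicate 2 or 3 or ddm1cmt2 replicate 2 or 3. The H3K9 methyltransferase SUVH6 (AT2G22740, 0.53 ± 0.10) rose. Another of the 3 was the demethylase gene IBM1, with an adjusted p of 0.0514 to 0.0965 without ddm1 replicate 1 or 3 or ddm1cmt2 replicate 1, 2 or 3 and 0.0552 with upper-quartile factors. In the demethylation list 2 of 9 rose and 2 fell (2 and 3 adjusted over the list alone). The median was 0.01 (camera adjusted p = 0.997). Rises numbered 1 without ddm1 replicate 2 or 3 or ddm1cmt2 replicate 2, and falls numbered 1 without ddm1 replicate 1 or ddm1cmt2 replicate 2 or 3. DML3 rose (1.49 ± 0.22) and IDM1 fell (-0.52 ± 0.14). Post-transcriptional silencing gave 4 of 9 that rose and 0 that fell (4 and 0 adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.484). The number risen was 2 without ddm1 replicate 1, 2 or 3 and 1 without ddm1cmt2 replicate 2. Of the DNA damage genes 1 of 18 rose and 3 fell (1 and 0 adjusted over the list alone). The median was 0.00 (camera adjusted p = 0.895). Risen members numbered 2 without ddm1 replicate 2, and fallen members numbered 1 without ddm1 replicate 1, 2 or 3 or ddm1cmt2 replicate 2 and 0 without ddm1cmt2 replicate 3. RAD17 was the 1 that rose (1.20 ± 0.19).

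The cold, drought and ABA list rose almost throughout: 10 of 11 rose and 0 fell (10 and 1 adjusted over the list alone). The median was 1.97 (camera adjusted p = 5.5e-18 and adjusted p = 0.00856 with an estimated correlation). Calls downward came to 1 without ddm1 replicate 2 or ddm1cmt2 replicate 1. Beyond this test, none of the 60 list tests passed under both correlations. Beside COR15A, the desiccation genes RD29A (AT5G52310, 3.63 ± 0.23), KIN2 (AT5G15970, 2.27 ± 0.11) and ERD10 (1.97 ± 0.13) rose. In the clock list 5 of 11 rose and 4 fell (5 and 4 adjusted over the list alone). The median was 0.01 (camera adjusted p = 0.0994). GI, PRR7 (4.53 ± 0.12), PRR5 (AT5G24470, 4.24 ± 0.18) and PRR9 (AT2G46790, 2.13 ± 0.25) rose, and LHY and ELF3 (-0.87 ± 0.12) fell, of which PRR9 and ELF3 are outside the rule for named genes and were chosen after their values were seen. For this list the adjusted p was 0.0355 without ddm1cmt2 replicate 1, 0.0268 without ddm1cmt2 replicate 2 and 0.0373 in a fit of the 2 groups alone. Morning-phased RVE2 (AT5G37260), a MYB-like factor, also fell (-4.22 ± 0.33), as did BBX32 (AT3G21150) (-3.96 ± 0.38), the inositol oxygenase gene MIOX4 (AT4G26260, -4.05 ± 0.73) and AT1G26790 (-6.66 ± 0.37, or -7.25 without ddm1cmt2 replicate 2). RVE2, BBX32 and AT1G26790 were not low in ddm1cmt2 alone. In ddm1nrpe1 they reached at most 13.96, 2.01 and 1.67 CPM, against at least 112, 20.6 and 27.2 in ddm1. More leaf photosynthesis markers rose than fell, as 8 of 14 rose and 1 fell (8 and 1 adjusted over the list alone). The median was 0.89 (camera adjusted p = 3.1e-07 and adjusted p = 0.518 with an estimated correlation). Among them were the antenna genes CAB3 (AT1G29910, 2.15 ± 0.17), LHCB3 (1.94 ± 0.15) and LHCA1 (1.94 ± 0.16) and the photosystem I gene PSAD1 (AT4G02770, 1.40 ± 0.12). The clock values above stand beside them as a measured difference between these libraries. Plastid-encoded genes fell in 74 of 110 cases with a median of -0.80.

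In the immune list 13 of 18 rose and 0 fell (17 and 0 adjusted over the list alone). The median was 2.39, also with the members at 0 counts at their bound (camera adjusted p = 8.5e-09 and adjusted p = 0.518 with an estimated correlation). RPP4 went from 13.9 ± 1.28 to 149 ± 14.1 CPM (3.42 ± 0.11) and PAD4 (AT3G52430), a partner of EDS1, and NPR1 rose by 1.03 ± 0.17 and 0.70 ± 0.11. Wound and jasmonate genes rose without exception among those called, since 8 of 12 rose and 0 fell (8 and 0 adjusted over the list alone). The median was 1.14 (camera adjusted p = 2.1e-05 and adjusted p = 0.201 with an estimated correlation). Examples are AOS (2.62 ± 0.13), LOX3 (2.45 ± 0.21), OPR3 (AT2G06050, 1.01 ± 0.18), an enzyme of the same pathway, and VSP2 (1.18 ± 0.24). For flavonoid genes 8 of 11 rose and 0 fell (9 and 0 adjusted over the list alone). The median was 1.31 (camera adjusted p = 1.0e-05 and adjusted p = 0.518 with an estimated correlation). CHI (1.50 ± 0.13), CHS (1.31 ± 0.12), FLS1 (1.36 ± 0.14) and F3H (1.10 ± 0.13) rose. Of the glucosinolate list 5 of 9 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 0.50 (camera adjusted p = 0.0267 and adjusted p = 0.665 with an estimated correlation). CYP83A1 (1.12 ± 0.15), the regulator MYB29 (AT5G07690, 1.05 ± 0.17) and the glucosyltransferase gene UGT74C1 (AT2G31790, 0.50 ± 0.10) rose. A fit of the 2 groups alone gave camera adjusted p = 0.0815. Heat shock genes gave 3 of 7 that rose and 0 that fell (3 and 0 adjusted over the list alone). The median was 0.90 (camera adjusted p = 0.194). The risen count was 1 without ddm1 replicate 1 or 3 or ddm1cmt2 replicate 3. HSP70 rose (0.88 ± 0.15). Loci at 0 counts in ddm1 included TPS03 (AT4G16740), a terpene synthase gene (at least 57.5-fold higher), GSTU12 (at least 26.9-fold) and the drought-related factor gene DREB2C (AT2G40340) (at least 16.3-fold). These values stand beside the fall of LHY and the rise of GI and beside a plastid share of 0.870%.

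Flowering genes gave 4 of 6 that rose and 1 that fell (4 and 1 adjusted over the list alone). The median was 1.37 (camera adjusted p = 0.0787). Rises numbered 2 without ddm1 replicate 2 or 3. FT (2.30 ± 0.48) and the floral integrator SOC1 (AT2G45660, 2.23 ± 0.12) rose and CO fell (-3.85 ± 0.37). Camera gave adjusted p = 0.0444 for it without ddm1 replicate 1 and 0.0329 without ddm1cmt2 replicate 2. In the cell division list 2 of 14 rose and 2 fell (2 and 2 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.771). The number risen was 1 without ddm1 replicate 1 or 2 or ddm1cmt2 replicate 1 or 2 and 4 without ddm1cmt2 replicate 3, and the number fallen was 0 without ddm1 replicate 2 or ddm1cmt2 replicate 3 and 1 without ddm1 replicate 3. The histone H3 gene AT5G65360 rose (0.54 ± 0.14). Few root markers passed the test, since 1 of 13 rose and 1 fell (1 and 0 adjusted over the list alone). The median was -0.03, where the mean was 0.29 and the test pointed down (camera adjusted p = 0.996). Risen members numbered 2 without ddm1 replicate 1, and fallen members numbered 0 without ddm1 replicate 1 or 3 or ddm1cmt2 replicate 1 or 2 and 2 without ddm1 replicate 2. The nitrate transporter gene NRT2.1 (AT1G08090, 3.03 ± 0.58) was the 1 that rose. Among senescence genes 2 of 7 rose and 1 fell (2 and 1 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.645). Calls upward came to 1 without ddm1 replicate 2 or 3 or ddm1cmt2 replicate 1 or 3. SAG29 rose (2.33 ± 0.34) and SEN1 (AT4G35770), a dark-induced gene, fell (-2.07 ± 0.37). GEX2 was uncalled at -0.23 ± 0.25, and AT1G21945 of the ONSEN list had -1.23 ± 0.30 (adjusted p = 0.00443).

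**Figure D4:**
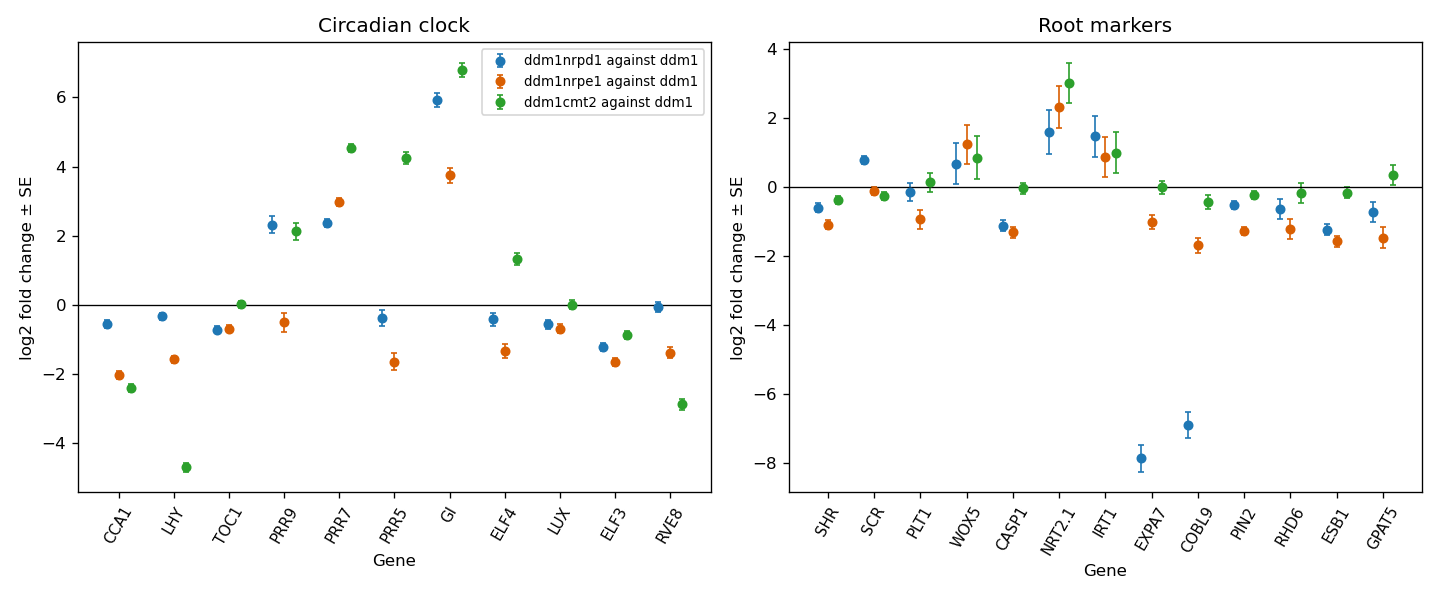
Log2 fold change ± standard error of 11 clock genes and 13 root markers in each double mutant against ddm1. GI rises in all 3 (5.93, 3.74 and 6.80), and the hair gene COBL9 falls to -6.90 in ddm1nrpd1.

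Direct tests between the double mutants show where they differ. Between ddm1nrpd1 and ddm1nrpe1, AT4TE15820 was higher in ddm1nrpd1 (6.72 ± 0.27), as was AT4TE15825 (10.27 ± 0.40, or 11.42 without ddm1nrpe1 replicate 3). The cell wall genes EXT11 and PRP1, at 0 counts in ddm1nrpd1, were at least 127-fold and at least 115-fold lower there. Of the root hair genes 11 of 11 were lower in ddm1nrpd1 than in ddm1nrpe1, with a median of -6.42, or -6.30 with members at 0 counts at their bound, a set formed after the values were seen. In all 4074 loci were higher and 4896 lower in ddm1nrpd1, 1058 and 1335 at least 2-fold, and the first count was 2640 without ddm1nrpe1 replicate 2. Of the TE loci 575 were lower in ddm1nrpd1 and 295 higher. Their odds ratio against other loci was 1.84 for lower (Fisher's exact test, p = 4.5e-29) and 0.920 for higher (p = 0.211). The median of the plastid genes between these groups was -0.06.

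In ddm1cmt2 against ddm1nrpd1, root hair genes and most plastid genes were higher, and more TE loci were lower than higher. EXT11, PRP1 and RHS12, at 0 counts in ddm1nrpd1, were at least 433-fold, at least 419.9-fold and at least 221-fold higher in ddm1cmt2, and 96 of 110 plastid genes were higher (median 2.94). AT2TE69490, AT4G12426 and AT2TE27505, at 0 counts in ddm1cmt2, were at least 35.6-fold, at least 33.9-fold and at least 33.7-fold lower. Here 6469 loci were higher and 6079 lower (1998 and 2444 at least 2-fold), and of TE loci 396 were higher and 797 lower (odds ratio 2.37 for lower, Fisher's exact test, p = 6.8e-66). Against ddm1nrpe1, ddm1cmt2 had more of AT4TE15825 (11.01 ± 0.40, or 12.17 without ddm1nrpe1 replicate 3), of the plastid gene ATCG01130 (10.09 ± 0.34) and of TPS03 (at least 112-fold), and less of AT2TE27505 (at least 35.0-fold). In that comparison 6686 loci were higher and 7001 lower (2197 and 2729 at least 2-fold), and of TE loci 309 were higher and 901 lower (odds ratio 2.44 for lower, Fisher's exact test, p = 6.3e-74). Plastid genes were higher in 97 of 110 cases (median 2.87).

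Genes called in the same direction in all 3 double mutants against ddm1 numbered 2593, 1351 higher and 1242 lower, and 163 of them were TE loci. Independent lists of these sizes would share 506. The 20 simulations of unchanged groups against the same ddm1 libraries gave 0 on average. Unchanged groups yield hardly any calls, so that 0 does not show what shared controls add to long lists. The ddm1nrpd1 and ddm1nrpe1 lists shared 3821 risen loci (1509 for independent lists), of which 499 were TE loci, and 3257 fallen loci (1289.6). Of all loci 440 went opposite ways (2790.3). For ddm1nrpd1 and ddm1cmt2 these numbers were 1942 (1047), 1765 (955) and 1108 (2000.0), and for ddm1nrpe1 and ddm1cmt2 they were 1931 (1211), 1889 (1054) and 1200 (2260.0). Across genes, which are not independent replicates, log2 fold changes of ddm1nrpd1 and ddm1nrpe1 had r = 0.75 (0.62 in the simulations) and a covariance of 0.893 (0.0496). With ddm1cmt2, r was 0.33 for ddm1nrpd1 (0.59 simulated) and 0.34 for ddm1nrpe1 (0.58), with covariances of 0.274 (0.0497) and 0.289 (0.0493). The simulated r comes from noise in the shared ddm1 libraries alone, so a lower observed r does not mean less agreement than by chance. The 3 ddm1 libraries are too few to split, so part of the excess may come from these shared controls.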

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

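All alternatives here were planned except the fit without organelle loci, which was chosen after seeing the data. No list or named gene changed direction among its called values, and the counts of calls over all loci and over TE loci stayed within 1.5 times under the other scalings, DESeq2, limma-voom, both filters, the 2 groups alone and without organelle loci (overlap of calls 2540, list shifts 22). Which side held more calls did depend on the scaling and the filter. With upper-quartile factors the counts higher and lower went from 5693 and 5388 to 5518 and 5575 in ddm1nrpd1, from 6582 and 5945 to 5796 and 6841 in ddm1nrpe1 and from 4569 and 4402 to 4019 and 5056 in ddm1cmt2 against ddm1, from 4074 and 4896 to 4679 and 4150 in ddm1nrpd1 against ddm1nrpe1 and from 6469 and 6079 to 5969 and 6455 in ddm1cmt2 against ddm1nrpd1. For ddm1cmt2 the side with more calls also turned with TE-free TMM (4436 and 4560 against ddm1 and 6190 and 6247 against ddm1nrpd1), with no filter (4383 and 4617, then 6124 and 6334), with the stricter filter (4366 and 4605, then 6070 and 6284) and without organelle loci (4367 and 4536, then 6025 and 6275), in the 2 groups alone against ddm1nrpd1 (5731 and 6124), and without ddm1 replicate 3 against ddm1 (3487 and 3651). Against ddm1nrpe1 it turned without ddm1cmt2 replicate 1, 2 or 3 (6350 and 6345, 5895 and 5814 or 6627 and 6597, from 6686 and 7001). The cause was not tested. Asking for at least 2-fold lowered the counts higher and lower to 2190 and 1565 in ddm1nrpd1, 2661 and 1902 in ddm1nrpe1 and 1487 and 1163 in ddm1cmt2 against ddm1, 1058 and 1335 in ddm1nrpd1 against ddm1nrpe1, 1998 and 2444 in ddm1cmt2 against ddm1nrpd1 and 2197 and 2729 against ddm1nrpe1. For TE loci the counts were 448 and 205, 537 and 184 and 67 and 181, and the overlap of calls fell from 2593 to 585, since fewer loci meet both conditions. Leaving out 1 library at a time, loci higher in ddm1nrpd1 than in ddm1nrpe1 ranged from 2640 to 4129 (the lowest without ddm1nrpe1 replicate 2) and those lower from 3384 to 4926, and calls against ddm1 from 4734 to 5214 and 4375 to 4844 in ddm1nrpd1, 5438 to 6514 and 4793 to 5946 in ddm1nrpe1 and 3487 to 4224 and 3651 to 3909 in ddm1cmt2, with fewer samples in the fit. The 21 list shifts fell to 1 with an estimated correlation and numbered 37 with fry, which tests a list without comparing it with other genes. Over the 311 named values, leaving out 1 library kept the side of the threshold in 1740 refits, ended the call in 119 and brought one in 7. Called members of a list, with the main count first, changed by over 1.5 times in these cases: in ddm1nrpd1 methyltransferase-list genes fallen 2 to 1 (block, 2 groups alone, DESeq2), post-transcriptional silencing genes risen 2 to 1 (block, DESeq2, limma-voom), flavonoid genes risen 5 to 8 (2 groups alone), cell division genes risen 2 to 4 (2 groups alone), cell division genes fallen 0 to 1 (2 groups alone), leaf genes fallen 1 to 2 (2 groups alone), root genes risen 1 to 2 (2 groups alone) and to 3 (DESeq2), then in ddm1nrpe1 methyltransferase-list genes risen 2 to 1 (RLE, upper-quartile, no filter, stricter filter, without organelle loci, block, 2 groups alone, DESeq2, limma-voom), methyltransferase-list genes fallen 3 to 6 (upper-quartile), post-transcriptional silencing genes fallen 0 to 1 (RLE, no filter, stricter filter, without organelle loci, 2 groups alone) and to 2 (upper-quartile), root genes risen 1 to 2 (limma-voom), then in ddm1cmt2 methyltransferase-list genes fallen 2 to 1 (2 groups alone), RdDM genes fallen 2 to 1 (DESeq2), post-transcriptional silencing genes risen 4 to 2 (upper-quartile), methylation-silenced genes fallen 2 to 1 (2 groups alone, limma-voom), wound and jasmonate genes risen 8 to 5 (2 groups alone), heat shock genes risen 3 to 1 (limma-voom), glucosinolate genes risen 5 to 3 (2 groups alone), cell division genes risen 2 to 1 (upper-quartile, block, 2 groups alone, limma-voom), cell division genes fallen 2 to 1 (block) and to 4 (2 groups alone), senescence genes risen 2 to 1 (upper-quartile, block, 2 groups alone, limma-voom). The cause was not tested. DESeq2 gave no adjusted p for 1 locus per comparison. Tests by transposon superfamily and by pericentromere were not run, because families and TAIR10 positions were not used here. Depth was lowest in ddm1, and its bearing on the calls was not tested, since no fit at matched depth was run.

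With the replicate block, the number as a term in the fit, calls were 5477 and 5185 in ddm1nrpd1, 6412 and 5795 in ddm1nrpe1 and 4382 and 4177 in ddm1cmt2 against ddm1, 3867 and 4636 in ddm1nrpd1 against ddm1nrpe1, 6271 and 5899 in ddm1cmt2 against ddm1nrpd1 and 6492 and 6806 against ddm1nrpe1, with TE loci at 605 and 461, 719 and 418 and 148 and 416, an overlap of 2422 and 21 list shifts. The numbers did not pair the samples: same-numbered libraries of 2 groups correlated in their deviations from the group means at r = -0.31 to 0.22, over 0.1 in 3 of 18 pairs, and 4 of 12 libraries matched their own number best.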

Other observations

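The gene families, the sets of root hair, small RNA and mitochondrial genes, and the 3 plastid tests and the root marker test were chosen after their values had been seen, whereas the clock outputs and the root hair regulators other than RHD6 were fixed before theirs were. Arabinogalactan proteins, proteoglycans of the cell surface (symbol AGP), fell in all 3 double mutants, 20 of 25 in ddm1nrpd1 (median -1.13, camera adjusted p = 7.8e-10), 19 in ddm1nrpe1 (median -0.96, camera adjusted p = 4.1e-05) and 19 in ddm1cmt2 (median -0.68, camera adjusted p = 4.2e-05). Their relatives with a fasciclin domain (FLA) fell in 11 of 14 cases in ddm1nrpd1 (median -0.78, camera adjusted p = 0.00210) and 10 in ddm1nrpe1 (median -0.78, camera adjusted p = 0.00162). Expansins, which loosen cell walls (EXPA), fell in 9 and 11 of 16 cases in ddm1nrpd1 and ddm1nrpe1 (median -0.43, camera adjusted p = 0.00628, then median -0.63, camera adjusted p = 0.00688), with EXPA7 of the root hair set, which also fell in these comparisons, among them. Genes named for irregular xylem (IRX) fell in ddm1nrpe1, 7 of 10 (median -1.11, camera adjusted p = 0.00713). Cysteine-rich receptor-like kinases (CRK) rose in 23 of 37 cases in ddm1nrpd1 (median 0.93, camera adjusted p = 0.00208) and in 30 in ddm1nrpe1 (median 1.30, camera adjusted p = 1.1e-05). Glutathione transferases of the phi class (GSTF) rose in 9 and 8 of 11 cases in these 2 double mutants (median 1.66, camera adjusted p = 0.0164, then median 1.16, camera adjusted p = 0.0327), and those of the tau class (GSTU) in 14 of 24 cases in ddm1cmt2 (median 0.76, camera adjusted p = 0.00208). In ddm1cmt2 the cytokinin response factors (CRF) fell in 7 of 11 cases (median -0.79, camera adjusted p = 4.1e-05). These come from 393 tests of 131 symbol stems with at least 10 members, adjusted together, and with an estimated correlation every stem had an adjusted p of at least 0.902.

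Root hair genes, defined as those with an RHS symbol and a number plus EXPA7 and COBL9, fell in 11 of 11 cases in ddm1nrpd1 (median -6.90, also with members at 0 counts at their bound) and in 7 in ddm1nrpe1 (median -0.90), and the median in ddm1cmt2 was 0.01. The fall in ddm1nrpe1 was not particular to hair genes. There the 10 root markers outside hairs had a median of -1.01 (1 rose, 6 fell). RHS8 (AT1G63450), RHS13 (AT4G02270) and RHS16 (AT4G29180), picked after their values were seen, fell in ddm1nrpd1 (-4.84 ± 0.42, -6.68 ± 0.50 and -5.05 ± 0.43), and RHS18 (AT5G22410) was at least 132-fold lower. Genes of snoRNAs, snRNAs and tRNAs were lowest in ddm1cmt2, where 15 of 35 fell against ddm1 (median -0.74), 25 were lower than in ddm1nrpd1 (median -1.19) and 23 were lower than in ddm1nrpe1 (median -1.14). In the same comparison of ddm1cmt2 with ddm1, plastid genes had a median of -0.80 (74 of 110 lower) and mitochondrial genes one of -0.52 (15 of 46 lower), and poly(A) selection that differed between the groups was not tested as a cause of the small RNA values.

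Plastid transcripts fell in ddm1nrpd1 and ddm1nrpe1 (medians of -3.84 and -3.74) in libraries that the labels describe as polyA RNA. A uniform loss of RNA without poly(A) tails would lower mitochondrial transcripts about as far, and against it the 7 mitochondrial loci with at least 100 counts over ddm1 had a median at least 2.96 above the plastid one, a set narrowed after all 46 loci (medians of -0.76 and -0.71) had been seen. The 35 snoRNA, snRNA and tRNA genes had medians of 0.25 in ddm1nrpd1 (10 rose, 2 fell) and -0.03 in ddm1nrpe1 (8 rose, 2 fell). These values also go against a uniform loss, though reads of overlapping genes may count among them. By share of counts the 2 classes lay closer than by these medians. Mitochondrial genes went from 0.0550% to 0.0181% and 0.0213%, and plastid genes from 1.75% to 0.223% and 0.232%. Abundant mitochondrial loci did fall, ATMG00020 (-2.40 ± 0.20 and -1.99 ± 0.19) and ATMG00030 (-1.75 ± 0.23 and -1.63 ± 0.23) among them, so a loss that differs among transcripts may still be part of it. Less photosynthetic tissue is argued against by the nuclear leaf markers, whose lower median of the 2 comparisons was -0.0471. It is not excluded, since in ddm1nrpe1 5 of the 14 markers rose and 4 fell. Light-harvesting genes are among these markers, and whether harvest time or clock phase moved them stays open. A preparation batch shared by these groups cannot be told apart from their shared loss of RdDM, since the plastid median between them was -0.0596 and either would give that, and an effect of genotype on plastid transcripts was not tested.

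The called genes of the clock list in ddm1cmt2 were LHY, CCA1, RVE8 and ELF3, which fell, and GI, PRR5, PRR7, PRR9 and ELF4, which rose, and a harvest later in the day could be part of this. Such a harvest would also move clock outputs outside the list, and the median of 5 dawn-phased outputs minus that of 5 afternoon- and dusk-phased ones was -2.69 (-1.23 against 1.47). The split was not particular to ddm1cmt2, as the medians against ddm1 were -1.85 against 0.20 in ddm1nrpe1, though -0.19 against -0.28 in ddm1nrpd1. In ddm1cmt2 FKF1 (AT1G68050), evening-phased, rose by 5.35 ± 0.31, and COL2 (AT3G02380) and RVE1 (AT5G17300), dawn-phased, fell (-2.48 ± 0.18 and -2.35 ± 0.35), but LNK1 (AT5G64170), dawn-phased, rose (2.52 ± 0.13), CDF1 (AT5G62430), dawn-phased, was uncalled (0.18 ± 0.14) and BOA (AT5G59570), evening-phased, fell (-2.21 ± 0.40). A clock phase altered by the genotype predicts the same values, so both stay open in ddm1cmt2 and ddm1nrpe1. Their bearing on the cold and light-harvesting genes stays open too. The close medians do not clear ddm1nrpd1, where 3 of 11 clock genes rose, GI by 5.93, and 5 fell. All 3 comparisons share the ddm1 libraries, so a harvest time or phase particular to ddm1 would bear on each. No harvest time is given in the sources used here.

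Root hair transcripts lay near 0 in ddm1nrpd1, and fewer roots in the sample would lower other root markers too. Those outside hairs had a median of -0.32, against -6.90 for the hair genes, which argues against fewer roots as the whole cause. A lower transcript of a hair transcription factor may be involved: RSL2 (AT4G33880), with 2 counts in ddm1nrpd1 and 75 in ddm1, had a ratio of 79.7 (counting interval 21.3 to 670.1; fitted -6.02), and RSL4 (AT1G27740) fell (-2.55 ± 0.36). RHD6 (AT1G66470), which acts above them, was uncalled at -0.63 ± 0.28 (adjusted p = 0.0795, or -0.81 and 0.0461 without ddm1 replicate 3), and RSL1 was not in the table. RSL2 could itself lie downstream of the change, and a second mutation or a heritable epigenetic state in this ddm1 line was not tested.

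The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 of 10 splits, the real one, gave as many calls. The real split and the highest other gave 11081 and 0 calls for ddm1nrpd1, 12527 and 0 for ddm1nrpe1 and 8971 and 6 for ddm1cmt2 against ddm1, 8970 and 2 between ddm1nrpd1 and ddm1nrpe1, 12548 and 0 for ddm1cmt2 against ddm1nrpd1 and 13687 and 0 against ddm1nrpe1. Every other split puts both genotypes on each side, so a difference between groups adds to the spread within sides. Few calls in those splits follow from this, and the size of the contrast decides nothing.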
